A study of Homo sapiens with 54 samples.

How the data were processed

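Subcutaneous fat was sampled from 14 volunteers before, and 4, 12 and 24 h after, an intravenous dose of 3 ng/kg lipopolysaccharide (LPS, or endotoxin, a component of the outer membrane of gram-negative bacteria), per the labels' protocols. RNA was extracted with a column kit made for lipid-rich tissue and labelled with biotin, per the labels' protocols, and was hybridised to Affymetrix expression arrays, on which each transcript is read by a set of short probes near its 3' end. There were 14 arrays before LPS, 14 at 4 h, 14 at 12 h and 12 at 24 h. Arrays were grouped by the time in their labels, and the volunteer was read from the number in each array's title and recoded.

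The authors deposited 1 table with a log2 signal for 34638 probe sets on each of the 54 arrays, which is part of the array's probe sets. The program MAS5 is named in the submitters' processing notes, with no version or role. The normalization, any filter on probe sets and the genome build were not given in the sources used here. The log2 scale and the fact that the arrays had been brought to a common level were read from the deposited values: the medians of the arrays lay between 7.51 and 7.95 and their 75th percentiles between 9.28 and 9.64. Such scaling sets the arrays against each other, so a change shared by most genes would not be seen in these values. The number of arrays limits the precision.

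Of the probe sets, 27491 carried 1 gene symbol, 1306 carried several and 5841 carried none in the annotation used, with 35 controls counted among them. The gene IDs of 27433 probe sets matched the reference table of human genes, from which current symbols were taken. Each gene was read by the probe set with the highest mean signal among those given to that gene alone, which left 14167 genes. XIST and Y-linked genes, 17 in number, were left out. Genes had to lie above the median of their own array on at least 12 arrays, the size of the smallest group, and 9940 genes were tested. No further normalization was applied.

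Genes were compared with limma 3.58.1 in R 4.3.3. All 54 arrays entered 1 linear model with time and, as a block, the volunteer. Moderated statistics with an intensity trend gave p-values, which were adjusted by the Benjamini-Hochberg method over the 9940 genes. A gene is said to have risen or fallen where its adjusted p was under 0.05. Changes are log2 differences with the standard error (SE) of the model, and the number of volunteers that showed the direction is given beside them. No background level was used, so a fold is approximate where a mean lies under the array medians. The 3 later times were each compared with the time before LPS and with each other. The pairing comes from the volunteer number and was checked: across the 78 pairs of arrays of the same volunteer, the correlation of their deviations from the group means lay between 0.189 and 0.864 with a median of 0.608, against a median of -0.05 between different volunteers, and 47 of the 54 arrays were closest to an array of their own volunteer.

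Before the data were examined, 29 gene lists were fixed from textbook knowledge, 17 of pathways and 12 of cell type markers, with 661 distinct genes, of which 571 were in the deposited table and 490 were tested. Of their symbols, 21 were older names and were updated. Lists were tested with limma's camera, which asks whether the genes of a list moved further one way than the other genes, with a preset correlation between genes of 0.01 and adjustment over the 29 lists. Camera with a correlation estimated for each list and fry, which asks whether the genes of a list moved one way on balance, were run beside it. An exact sign-flip test over volunteers of each list's mean change relative to all genes was added after the data were seen. The named genes also followed a rule fixed before the data were examined. They were the 12 largest rises and 8 largest falls per time among genes that passed and moved that way in at least 80% of the volunteers, the 5 largest rises and falls of 24 h against 4 h and against 12 h, up to 2 rises and 2 falls per list and time, and a panel of 18 genes. Of the panel, TNF and SLC2A4 did not pass the intensity filter.

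RNA quality was read from the control probe sets of GAPDH and ACTB as the log2 ratio of the signal near the 3' end to that near the 5' end, which rises as RNA is degraded. Each later time was compared with the time before LPS by an exact two-sided sign-flip test over volunteers. The arrays were also described by their mean correlation with the other arrays.

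The gene model and the list test were tested on simulated data with the real arrays' means and spread, in 5 runs of 9940 genes with 200 genes changed in each. For the 4 h comparison 69% of the genes changed by 0.5 on the log2 scale and 95.6% of those changed by 1 were recovered. The shares were 70.8% and 95.2% for 12 h and 67% and 94.6% for 24 h. Between 8.4 and 8.8 unchanged genes were called per run on average. All 5 shifted lists of 20 genes were called. The simulated spread of a gene was the same at all times, and genes were drawn independently of each other. The simulations therefore do not cover a wider spread of the 24 h arrays or correlation between the genes of a list.

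Alternatives concerned the volunteer block (no block, or the volunteer as a random effect), the arrays in the fit (volunteers with all 4 times, or only both groups compared), the scaling (quantile normalization, arrays centred on their median), an offset on the linear scale, the intensity filter (no filter, or the 75th percentile), the choice of probe sets (their mean, or without the probe sets marked as cross-hybridising), the control ratio as a covariate, the intensity trend, arrays that carry marks in their titles, each volunteer left out in turn, and the list test. Alternatives chosen after the data were seen were array weights, leaving out 11 arrays with a mean correlation under 0.9 with the others, and leaving out the 4 volunteers whose array before LPS had a control ratio over 3. Probe sets without a symbol took no part in the main comparisons.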

Results

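Subcutaneous fat of healthy volunteers was profiled on 54 expression arrays before and after an intravenous dose of LPS, which activates toll-like receptor 4 and evokes a short systemic inflammation. There were 14 arrays before LPS, 14 at 4 h, 14 at 12 h and 12 at 24 h, from 14 volunteers, and 9940 genes were compared. The number of arrays limits the precision. The correlation between arrays ranged from 0.665 to 0.990, and 11 arrays had a mean correlation under 0.9 with the others. Of these, 3 were taken before LPS, 3 at 4 h, 2 at 12 h and 3 at 24 h. The 3' to 5' control ratio, a measure of RNA degradation, was 2.67 ± 1.16 (SD, n = 14, log2) before LPS, 2.05 ± 0.37 (n = 14) at 4 h, 1.99 ± 0.37 (n = 14) at 12 h and 1.86 ± 0.42 (n = 12) at 24 h. Within volunteers it differed from the time before LPS by -0.62 at 4 h (lower in 8 of 14, exact p = 0.0719), by -0.68 at 12 h (lower in 9 of 14, exact p = 0.0421) and by -0.84 at 24 h (lower in 9 of 12, exact p = 0.0137). Without the 4 volunteers with a ratio over 3 before LPS these differences were 0.01, -0.04 and -0.17.

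The comparison of 4 h with the time before LPS asked which transcripts differed early after the dose. All volunteers received LPS, so there is no series without it. At every time a change may therefore also come from the hour of the biopsy or from repeated sampling. The 12 largest rises included 5 chemokine genes. CXCL10, an interferon-induced chemokine that attracts T cells, rose 47.4-fold, from a log2 signal of 6.59 ± 1.68 (SD, n = 14) to 12.16 ± 0.66 (SD, n = 14). It was higher in 14 of 14 volunteers (log2 change 5.57 ± 0.34, adjusted p = 6.99e-17). CXCL11, a ligand of the same receptor, rose 24.4-fold (4.61 ± 0.31) in 14 of 14 volunteers. IL6, the main inducer of the hepatic acute phase response, rose 19.2-fold (4.26 ± 0.42), also in 14 of 14. CXCL2, a neutrophil chemokine, rose 19.0-fold, CCL2, a monocyte chemokine, 10.6-fold, and ICAM1, an endothelial adhesion molecule for leukocytes, 11.6-fold, each in 14 of 14 volunteers. The other rises among the 12 largest were those of LRG1, the phospholipase gene PLA1A, CX3CL1, PTX3, IDO1 and GBP1, between 10.7- and 16.8-fold. The largest falls were those of OR51E1, an olfactory receptor gene (7.08-fold, log2 change -2.82 ± 0.33), and of TRIL, which encodes an accessory protein of toll-like receptor 4 (6.96-fold, -2.80 ± 0.22), each lower in 14 of 14 volunteers. PRAG1, FAM124B, SERTAD4, CPVL-AS2, IRAG2 and EMX2 fell between 4.04- and 5.50-fold. The mean signals before LPS of CXCL10, CXCL11 (4.89), IL6 (6.13) and CXCL2 (7.17) lay under every array median, as did the 4 h means of the genes with the largest falls, and were not shown to lie above background, so these folds are approximate.

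Lists of inflammatory, glucocorticoid response and immediate early genes rose together at 4 h. The data hold no hormone levels, so what raised the glucocorticoid response genes was not tested. All 42 measured interferon response genes rose, with a median log2 change of 1.27 (42 adjusted over the list alone). Of 34 fixed cytokine and chemokine genes 19 were tested, and 14 of these rose (14 adjusted over the list alone, median 2.16). The 14 arrays at 4 h alone can carry a gene through the intensity filter. The tested genes may thus favour those that rose at that time. Of 19 NF-kB target and feedback genes 16 rose (16 adjusted over the list alone, median 1.45). Among them were SELE, which captures leukocytes on activated endothelium (2.98 ± 0.25), and NFKBIA, an inhibitor of NF-kB (1.79 ± 0.13). In the acute phase and STAT3 list 16 of 27 rose and 1 fell (16 and 1 adjusted over the list alone, median 0.75). SERPINA3, an acute phase protease inhibitor, rose by 3.28 ± 0.31 and SOCS3, a feedback inhibitor of cytokine signalling, by 2.60 ± 0.26, while IL6R fell by 0.39 ± 0.15. Of 22 glucocorticoid response genes 17 rose (18 adjusted over the list alone, median 0.81). They included FKBP5, a co-chaperone of the glucocorticoid receptor (2.16 ± 0.12), and the metallothionein gene MT1M (3.08 ± 0.18). Of 16 immediate early genes 10 rose (10 rose and 1 fell adjusted over the list alone, median 0.92). ATF3 rose by 2.06 ± 0.26 and DUSP5 by 2.04 ± 0.21. These 6 lists were called by camera and also with an estimated correlation. Its adjusted p = 0.00129 for interferon response, 0.000725 for cytokines, 8.62e-05 for NF-kB, 0.00063 for acute phase, 0.00013 for glucocorticoid response and 0.0301 for immediate early genes.

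**Figure D1:**
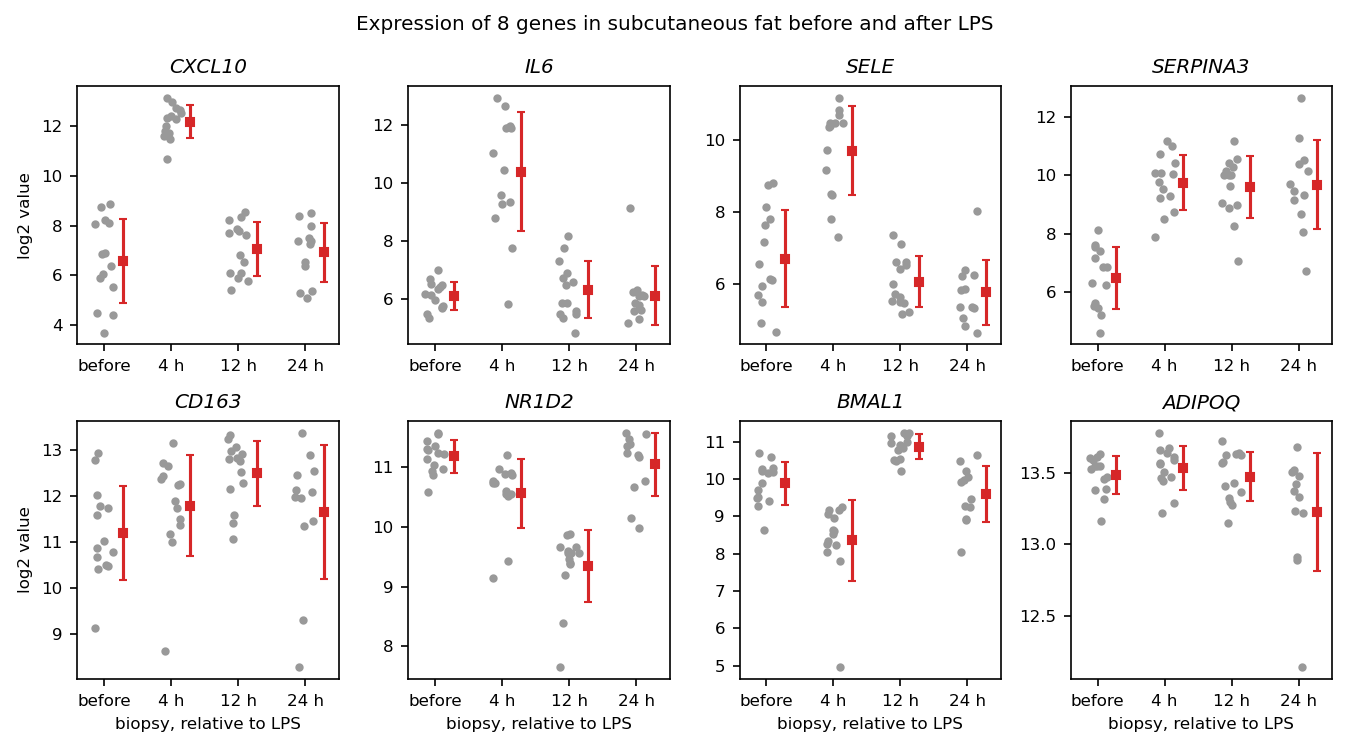
Log2 signal (y axis) of 8 genes in subcutaneous fat by time of biopsy (x axis); grey points are arrays (14, 14, 14 and 12 per time), red squares and bars are the mean ± SD. CXCL10 rose from a mean of 6.59 before LPS to 12.16 at 4 h, IL6 and SELE were also highest at 4 h, and SERPINA3 stayed higher at all 3 later times (log2 changes 3.28, 3.14 and 3.20).

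Markers of blood and vessel cells also moved at 4 h. Of 17 neutrophil and blood monocyte markers 7 rose (7 adjusted over the list alone, median 0.59; adjusted p = 0.484 with an estimated correlation). S100A12, a granulocyte calcium-binding protein, rose by 2.87 ± 0.45 and CLEC4E, a myeloid pattern receptor, by 2.05 ± 0.27. Of 25 fixed T and NK cell markers 9 were tested, and 8 of these fell (8 adjusted over the list alone, median -0.80, adjusted p = 0.636 with an estimated correlation). CD3D, a chain of the T cell receptor complex, was at -1.11 ± 0.23 and KLRB1, an NK cell receptor, at -1.11 ± 0.22. Of 19 endothelial markers 8 fell (9 adjusted over the list alone, median -0.25; adjusted p = 0.766 with an estimated correlation). CLEC14A fell most (-1.28 ± 0.14), followed by ENG, a co-receptor of the TGF-beta family (-1.24 ± 0.15). In the unfolded protein and heat shock list 8 of 19 rose and 1 fell (9 and 1 adjusted over the list alone, median 0.15; adjusted p = 0.138 with an estimated correlation). The heat shock gene HSPH1 was at 1.39 ± 0.17, XBP1 at 0.79 ± 0.11 and DDIT3 at -0.45 ± 0.13. In the toll-like receptor machinery list 4 of 24 rose and 1 fell (4 and 1 adjusted over the list alone, median 0.04; adjusted p = 0.449 with an estimated correlation). TLR2 was at 1.73 ± 0.22, RIPK2 at 1.30 ± 0.14 and SIGIRR, an inhibitory receptor of the family, at -0.40 ± 0.09. TLR4 itself was at 0.37 ± 0.19 (adjusted p = 0.129, higher in 10 of 14).

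Camera did not call the metabolic lists at 4 h, but the exact two-sided sign-flip test of their mean change relative to all genes called 4 of them. The shift was 0.18 for insulin signalling (higher in 14 of 14, adjusted exact p = 0.000393), 0.14 for adipokines (14 of 14, adjusted exact p = 0.000393), 0.07 for hypoxia and glycolysis (12 of 14, adjusted exact p = 0.0043) and 0.11 for lipolysis and lipid droplet (11 of 14, adjusted exact p = 0.0291). With an estimated correlation camera gave these 4 lists adjusted p = 0.419, 0.766, 0.766 and 0.909. The median change of all genes was -0.09, so a shift relative to all genes need not be a rise. The mean changes of the 4 lists themselves were 0.11, 0.08, 0.00 and 0.05. In insulin signalling 6 of 23 genes rose and 3 fell (6 and 3 adjusted over the list alone, median 0.06). IRS1, the insulin receptor substrate, fell by 0.59 ± 0.13 (adjusted p = 0.000382, lower in 13 of 14) and AKT2 fell by 0.45 ± 0.15. PIK3R1, the regulatory subunit of PI3-kinase, rose by 0.92 ± 0.13 and TRIP10 by 0.86 ± 0.18. INSR was at 0.07 ± 0.07 (adjusted p = 0.459, higher in 9 of 14). In lipolysis and lipid droplet 3 of 21 rose and 2 fell (3 and 2 adjusted over the list alone, median 0.02). ADRB3, the beta-3 adrenergic receptor, and ABHD5, a co-activator of triglyceride lipase, rose by 0.90 ± 0.22 and 0.61 ± 0.16. CIDEB fell by 0.98 ± 0.14 and G0S2, an inhibitor of that lipase, fell by 0.44 ± 0.12. In fatty acid and triglyceride synthesis 1 of 24 rose and 4 fell (1 and 2 adjusted over the list alone, median -0.13 although camera's direction was up). LPIN1 was at 0.52 ± 0.12, ELOVL6 at -0.74 ± 0.29 and GPAT3 at -0.63 ± 0.17. Of 13 adipokine genes only NAMPT rose (1 adjusted over the list alone, median 0.02, change 1.34 ± 0.17); ADIPOQ was at 0.05 ± 0.08 (adjusted p = 0.671, higher in 9 of 14) and LEP at 0.15 ± 0.13 (adjusted p = 0.412, higher in 9 of 14). LIPE was at -0.26 ± 0.15 (adjusted p = 0.193, lower in 12 of 14) and FASN at 0.26 ± 0.24 (adjusted p = 0.423, higher in 9 of 14). Adipogenic regulators moved both ways, 8 of 25 rising and 9 falling (8 and 9 adjusted over the list alone, median -0.06 although camera's direction was up). CEBPD was at 1.52 ± 0.17, STAT5A at 0.71 ± 0.09 and PPARG, the master regulator of fat cell differentiation, at 0.64 ± 0.20 against KLF2 at -1.21 ± 0.19 and GATA2 at -1.17 ± 0.17. Hypoxia and glycolysis genes also moved both ways, 4 of 24 rising and 5 falling (4 and 5 adjusted over the list alone, median -0.02 with a mean of 0.00 and camera's direction up). SLC2A3, a glucose transporter, was at 1.29 ± 0.22, HIF1A at 0.79 ± 0.11, the histone demethylase gene KDM3A at -1.28 ± 0.16 and ADM at -0.46 ± 0.15.

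Camera did not call the remaining lists at 4 h, but the other tests called some of them. The exact two-sided sign-flip test called fibroblast and progenitor (lower in 12 of 14, shift -0.18, adjusted exact p = 0.00109), B and plasma cell (lower in 11 of 14, shift -0.57, adjusted exact p = 0.00729) and skin epithelium (higher in 13 of 14, shift 0.50, adjusted exact p = 0.000708), for which camera with an estimated correlation gave adjusted p = 0.888, 0.766 and 0.766. Fry called the clock list (adjusted p = 0.0143), B and plasma cell (0.0125) and fibroblast and progenitor (0.0393), each down. Circadian clock genes gave 2 rises and 6 falls among 16 (3 and 7 adjusted over the list alone, median -0.17). NFIL3 was at 1.85 ± 0.15, PER2 at 0.43 ± 0.16, BMAL1, a core activator of the clock, at -1.53 ± 0.19 and DBP at -1.16 ± 0.19. Of 43 oxidative phosphorylation genes 4 fell (median -0.10), among them ATP5F1C (-0.19 ± 0.07) and COX4I1 (-0.17 ± 0.07), and none adjusted over the list alone with limma. Of 25 matrix and tissue repair genes 5 fell (4 adjusted over the list alone, median -0.18). MMP14 was at -0.52 ± 0.12 and THBS2 at -0.40 ± 0.10. Of 15 fibroblast and progenitor markers 4 fell (7 adjusted over the list alone, median -0.20). CD34 was at -0.82 ± 0.17 and SFRP2 at -0.72 ± 0.20. Among 18 macrophage markers CD163, the hemoglobin scavenger receptor, rose by 0.60 ± 0.23 and CSF1R fell by 0.69 ± 0.16 (1 fall adjusted over the list alone; median -0.02 although camera's direction was up). IGHM fell among 4 B and plasma cell markers (-1.15 ± 0.30; 2 falls adjusted over the list alone, median -0.62), HPGDS among 5 mast cell markers (-0.92 ± 0.23; 1 rise and 2 falls adjusted over the list alone, median -0.05) and KCNJ8 among 9 smooth muscle and pericyte markers (-0.79 ± 0.16; 1 adjusted over the list alone, median -0.14). PKP1 rose among 3 skin epithelium markers (1.59 ± 0.25; 1 adjusted over the list alone, median -0.12 and mean 0.44, camera's direction up). With limma 0 of 17 adipocyte markers were called (0 adjusted over the list alone, 2 at an unadjusted p under 0.05; median 0.01, mean -0.02, camera's direction up). Limma also called 0 of 7 red blood cell markers (0 adjusted over the list alone, 0 at an unadjusted p under 0.05; median 0.14) and 0 of 2 skeletal muscle markers (0 adjusted over the list alone, 0 at an unadjusted p under 0.05; median -0.09 although camera's direction was up).

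Across all genes 1042 rose and 2144 fell at 4 h, 240 and 164 of them at least 2-fold. Camera called 11 lists, 9 up and 2 down, fry 14 and the exact sign-flip test 18. Without the volunteer block 551 genes were higher and 672 lower. With array weights 1613 genes were higher, and without the 4 volunteers with a high control ratio before LPS 922 were lower.

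**Figure D2:**
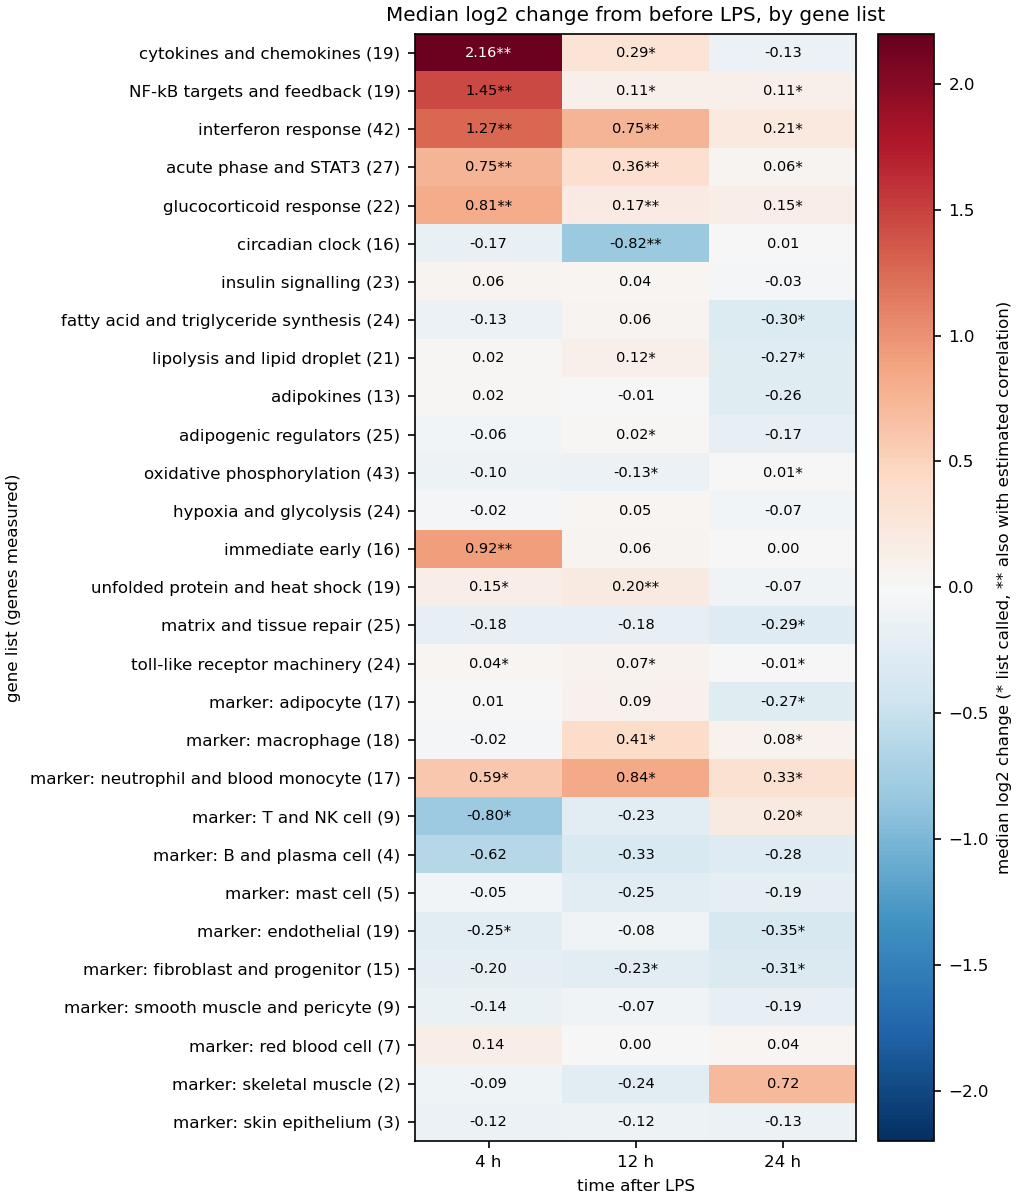
Median log2 change from the time before LPS (color and number) of each gene list (y axis, with the number of measured genes) at 4, 12 and 24 h (x axis); * marks a list called by camera and ** one that is also called with an estimated correlation. The cytokine list had the largest median at 4 h (2.16), the clock list the lowest at 12 h (-0.82), and no list has ** at 24 h.

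The comparison of 12 h with the time before LPS asked which transcripts differed later on. Its 12 largest rises included acute phase, myeloid and interferon-induced genes, and its 8 largest falls included 5 clock genes. PLA1A, a phosphatidylserine-specific phospholipase, rose 12.3-fold (3.62 ± 0.25, higher in 14 of 14, adjusted p = 3.95e-14) and SERPINA3 8.80-fold (3.14 ± 0.31, 14 of 14). CXCL9, an interferon-gamma-induced chemokine, rose 5.63-fold (2.49 ± 0.27, 14 of 14) and HP, the hemoglobin carrier haptoglobin, 5.22-fold (2.38 ± 0.25, 13 of 14). CIART, a repressor within the circadian clock, fell 6.98-fold (-2.80 ± 0.20, lower in 14 of 14, adjusted p = 7.02e-14), and the nuclear receptor gene NR1D2 fell 3.55-fold (-1.83 ± 0.10, 14 of 14). Other large rises were those of S100A12, MT1M, MCEMP1, MGAM, IDO1 and PROK2, between 3.92- and 5.48-fold. FCGR1A and FCGR1BP rose 5.27- and 5.57-fold, near-identical copies whose probe sets cannot be relied on to tell them apart. Other large falls were those of ERBB4, NAV3, TEF, PER3, C8orf34 and DBP, between 3.11- and 3.58-fold.

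Of 16 clock genes 11 fell and 4 rose at 12 h (11 and 5 adjusted over the list alone, median -0.82; adjusted p = 0.0154 with an estimated correlation). BMAL1 rose by 0.99 ± 0.19 and NFIL3 by 1.21 ± 0.15. Of 42 interferon response genes 35 rose (39 adjusted over the list alone, median 0.75). Of 27 acute phase and STAT3 genes 10 rose and SOCS2 fell by 0.53 ± 0.15 (13 and 1 adjusted over the list alone, median 0.36). Of 22 glucocorticoid response genes 10 rose (10 adjusted over the list alone, median 0.17, FKBP5 1.65 ± 0.12). Each of these 3 lists had adjusted p = 0.00688 with an estimated correlation. Of 19 unfolded protein and heat shock genes 9 rose (9 adjusted over the list alone, median 0.20; adjusted p = 0.0204 with an estimated correlation). The endoplasmic reticulum chaperone genes HYOU1 (0.98 ± 0.15) and PDIA4 (0.94 ± 0.11) led them. Of 17 neutrophil and blood monocyte markers 7 rose (11 adjusted over the list alone, median 0.84; adjusted p = 0.192 with an estimated correlation). S100A9 was at 1.82 ± 0.33. Of 18 macrophage markers 6 rose (8 adjusted over the list alone, median 0.41; adjusted p = 0.457 with an estimated correlation). CD163 was at 1.31 ± 0.23 (adjusted p = 9.11e-05, higher in 14 of 14) and LYVE1 at 1.16 ± 0.22. Of 24 toll-like receptor machinery genes 3 rose and 1 fell (3 and 2 adjusted over the list alone, median 0.07; adjusted p = 0.296 with an estimated correlation). The LPS carrier gene LBP was at 1.45 ± 0.27, the LPS co-receptor gene CD14 at 1.10 ± 0.14 and TLR7 at -0.68 ± 0.21. Of 19 cytokine genes 4 rose and 1 fell (5 and 1 adjusted over the list alone, median 0.29; adjusted p = 0.344 with an estimated correlation). CCL18 was at 1.19 ± 0.34, CCL2 at 1.09 ± 0.27 and IL33 at -0.86 ± 0.15. IL6 was at 0.19 ± 0.42 (adjusted p = 0.79, higher in 7 of 14) and CXCL10 at 0.46 ± 0.34 (adjusted p = 0.374, higher in 7 of 14). Of 19 NF-kB genes 4 rose (4 rises and 1 fall adjusted over the list alone, median 0.11; adjusted p = 0.44 with an estimated correlation). GCH1 was at 0.90 ± 0.22.

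Metabolic and stromal lists also held calls at 12 h. Of 21 lipolysis and lipid droplet genes 3 rose and 1 fell (3 and 1 adjusted over the list alone, median 0.12; adjusted p = 0.75 with an estimated correlation). PNPLA3 was at 0.98 ± 0.24, the droplet coat gene PLIN2 at 0.78 ± 0.12 and MGLL, which releases the last fatty acid of a triglyceride, at -0.31 ± 0.09. Of 25 adipogenic regulators 4 rose and 2 fell (5 and 2 adjusted over the list alone, median 0.02; adjusted p = 0.222 with an estimated correlation). PPARGC1B was at 0.59 ± 0.16, PPARG at 0.59 ± 0.20 and PPARD at -0.53 ± 0.12. Of 43 oxidative phosphorylation genes 9 fell (12 adjusted over the list alone, median -0.13; adjusted p = 0.75 with an estimated correlation). NDUFA5 was at -0.31 ± 0.08. Of 15 fibroblast and progenitor markers 6 fell (8 adjusted over the list alone, median -0.23; adjusted p = 0.344 with an estimated correlation). SFRP2 was at -1.14 ± 0.20 and LUM, a matrix proteoglycan, at -0.52 ± 0.09. IRS1 was at -0.34 ± 0.13 (adjusted p = 0.059, lower in 11 of 14) and ADIPOQ at -0.01 ± 0.08 (adjusted p = 0.945, lower in 8 of 14). TBC1D4, which controls glucose transporter traffic, fell by 0.44 ± 0.07.

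In all, 546 genes rose and 1101 fell at 12 h, 63 and 32 of them at least 2-fold, and 14 lists were called, 11 up and 3 down, against 7 with fry and 13 with the exact sign-flip test. Without the volunteer block the counts were 85 and 94, without the 4 volunteers with a high control ratio 153 and 143, and with that ratio as a covariate 344 and 469. With array weights 962 genes were higher. Without volunteer 11 there were 609 genes lower.

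**Figure D3:**
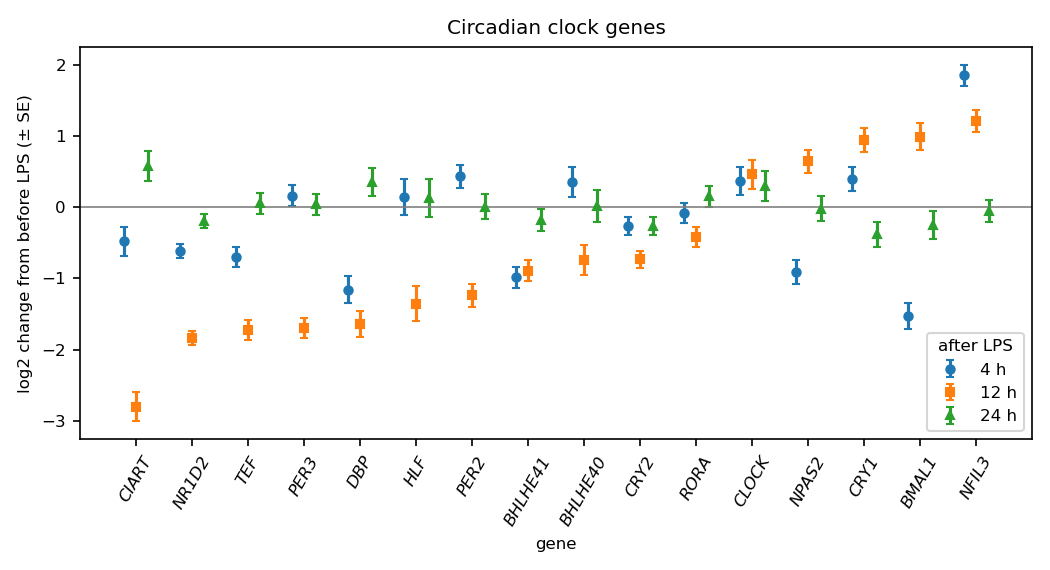
Log2 change from the time before LPS (y axis, ± SE) of the 16 measured circadian clock genes (x axis) at 4, 12 and 24 h after LPS (symbols). CIART reached -2.80 and NR1D2 -1.83 at 12 h, BMAL1 went from -1.53 at 4 h to 0.99 at 12 h, and no clock gene was called at 24 h with limma (3 at an unadjusted p under 0.05).

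The comparison of 24 h with the time before LPS asked which transcripts still differed a day later. SERPINA3 rose 9.19-fold (3.20 ± 0.32, adjusted p = 1.38e-08) and CXCL9 4.09-fold (2.03 ± 0.28, adjusted p = 2.26e-05), each in 12 of 12 volunteers, and HP rose 3.86-fold (1.95 ± 0.27, 10 of 12 volunteers). The metallothionein genes MT1G, MT1F and MT2A rose by 0.86 ± 0.15, 0.77 ± 0.14 and 0.76 ± 0.12, each in 11 of 12. GPX3, a secreted glutathione peroxidase, rose by 0.84 ± 0.14 in 9 of 12. The largest falls were those of LINC02996 (2.73-fold, -1.45 ± 0.22, lower in 12 of 12), CSMD1 (2.70-fold, -1.43 ± 0.26, 11 of 12) and C8orf34 (2.58-fold, -1.37 ± 0.27, 12 of 12). TNMD, a membrane protein of fat and tendon, fell 2.33-fold (-1.22 ± 0.24, 10 of 12). Further rises were those of H2BC5, MS4A7, PDZK1IP1, GUSBP14, CORO1A and SPI1, between 1.69- and 1.91-fold. Further falls were those of GRHL1, PCDH7, MCOLN3 and LHCGR, between 2.22- and 2.27-fold. None of these further 10 genes was called without the 11 arrays of low mean correlation.

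Across all genes 113 rose and 1252 fell at 24 h, 3 and 22 of them at least 2-fold, but this count rested on the arrays in the fit. The residual SD of the model averaged 0.333 over the 24 h arrays against 0.267 before LPS. With only the arrays of both times in the fit 5 genes were higher and 2 lower, and without the volunteer block 9 and 4. The counts were 18 and 193 with the control ratio as a covariate, 75 and 184 with array weights, and 47 and 70 without the 11 arrays. Of the genes that rose, 18 were called both with array weights and without the 11 arrays, among them SERPINA3, CXCL9, HP, MT1G, MT1F, MT2A and GPX3. Of those that fell 50 were, among them LINC02996, CSMD1, C8orf34 and TNMD, with -1.07, -1.32, -0.80 and -0.69 without the arrays. In the fit of only the arrays of both times HP (adjusted p = 0.0649), MT1G (0.0649), MT1F (0.0859), GPX3 (0.0975), CSMD1 (0.0975), C8orf34 (0.0714) and TNMD (0.108) lost their call. Called under all 3 settings were 5 rises (SERPINA3, CXCL9, MT2A, FKBP5 and MT1E) and 1 fall (LINC02996), of which MT1E was chosen after its values were seen. Without volunteer 2, 59 genes were higher and 537 lower, and without volunteer 5, 63 and 610. Without volunteer 13, 68 were higher, and without volunteer 1, 563 were lower.

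Camera called 15 lists at 24 h, 9 up and 6 down, and fry 10. Without the 11 arrays camera called 5 lists, and with array weights 6. With an estimated correlation camera called 0 lists, and 3 had an unadjusted p under 0.05. The exact sign-flip test called 3, glucocorticoid response (higher in 12 of 12, adjusted exact p = 0.0142), interferon response (11 of 12, 0.0283) and acute phase and STAT3 (10 of 12, 0.0425). Of 22 glucocorticoid response genes 6 rose and MAOA fell (7 and 1 adjusted over the list alone, median 0.15; adjusted p = 0.158 with an estimated correlation). Of 27 acute phase and STAT3 genes 2 rose and 1 fell (3 and 2 adjusted over the list alone, median 0.06; adjusted p = 0.331 with an estimated correlation). Of 42 interferon response genes 7 rose (8 adjusted over the list alone, median 0.21; adjusted p = 0.448 with an estimated correlation). Of 24 fatty acid and triglyceride synthesis genes 8 fell (10 adjusted over the list alone, median -0.30), and THRSP and SREBF1, regulators of lipogenesis, were at -0.72 ± 0.15 and -0.65 ± 0.15. Of 21 lipolysis and lipid droplet genes 7 fell (10 adjusted over the list alone, median -0.27). PNPLA3 was at -0.98 ± 0.26. Of 17 adipocyte markers 5 fell (8 adjusted over the list alone, median -0.27). Of 25 matrix and tissue repair genes 11 fell (1 rise and 15 falls adjusted over the list alone, median -0.29), and of 15 fibroblast and progenitor markers 5 fell (14 adjusted over the list alone, median -0.31). Of 19 endothelial markers 5 fell (12 adjusted over the list alone, median -0.35). LOX was at -0.67 ± 0.22, LUM at -0.51 ± 0.09 and EMCN at -0.63 ± 0.15. For each of these 6 lists adjusted p = 0.546 with an estimated correlation. Without the 11 arrays PNPLA3 was at -0.62, LOX at -0.08, LUM at -0.27 and EMCN at -0.26, none of them called, and neither MAOA nor SREBF1 was called.

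In the NF-kB list SOD2 rose at 24 h and SELE and VCAM1 fell (1 and 2 adjusted over the list alone; median 0.11 and mean -0.02, camera's direction up; adjusted p = 0.546 with an estimated correlation). Without the 11 arrays none of the 3 was called, with SELE at -0.97 (adjusted p = 0.0634) and VCAM1 at -0.34 (adjusted p = 0.33). With limma no gene was called in 5 lists that camera placed above the other genes. They were oxidative phosphorylation (0 adjusted over the list alone, 2 of 43 at an unadjusted p under 0.05; median 0.01, adjusted p = 0.689 with an estimated correlation), toll-like receptor machinery (0 adjusted over the list alone, 4 of 24 at an unadjusted p under 0.05; median -0.01 and mean 0.05, adjusted p = 0.546 with an estimated correlation) and macrophage (0 adjusted over the list alone, 3 of 18; median 0.08, adjusted p = 0.576 with an estimated correlation). The others were neutrophil and blood monocyte (0 adjusted over the list alone, 4 of 17; median 0.33, adjusted p = 0.546 with an estimated correlation) and T and NK cell (0 adjusted over the list alone, 2 of 9; median 0.20, adjusted p = 0.546 with an estimated correlation). The adiponectin gene ADIPOQ fell by 0.26 ± 0.08 (adjusted p = 0.0367, lower in 11 of 12) and was at -0.06 and not called without the 11 arrays. It belonged with TNMD and RBP4, which also lost its call without those arrays, to the 4 of 13 adipokine genes that fell. IL6 was at -0.14 ± 0.44 (adjusted p = 0.849, lower in 8 of 12) and CCL2 at -0.27 ± 0.29 (adjusted p = 0.541, lower in 7 of 12). IRS1 was at -0.35 ± 0.14 (adjusted p = 0.0769, lower in 11 of 12) and PPARG was at -0.44 ± 0.21 (adjusted p = 0.136, lower in 7 of 12).

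**Figure D4:**
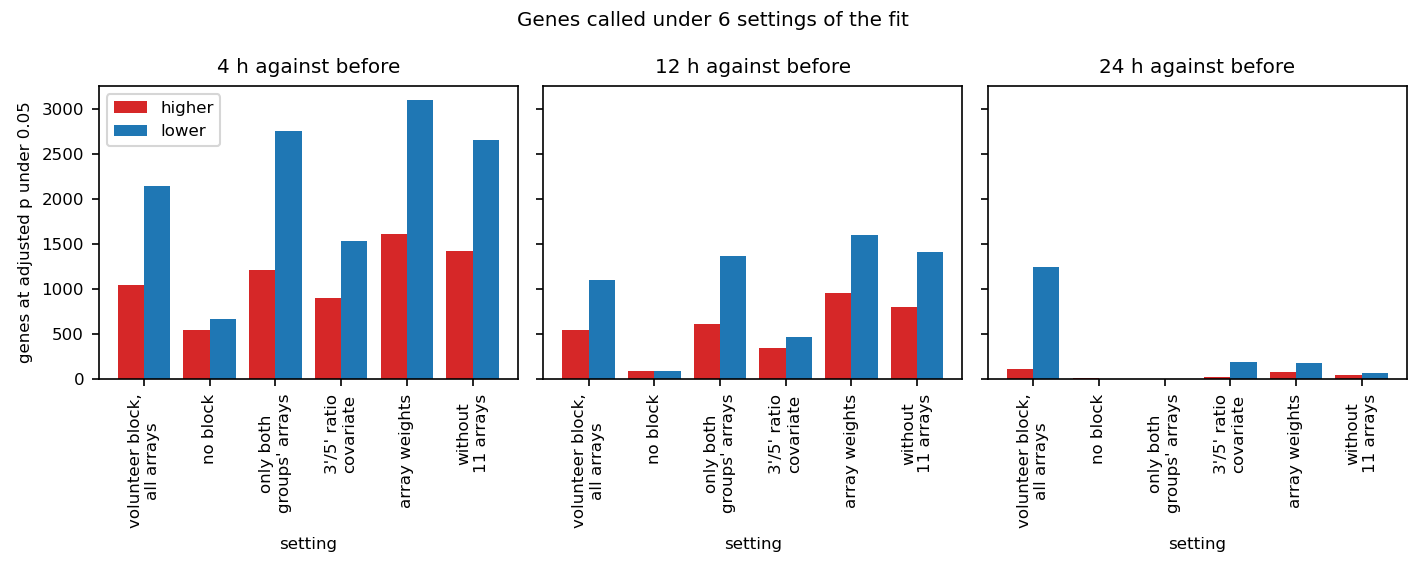
Number of genes with an adjusted p under 0.05 (y axis) that were higher (red) or lower (blue) than before LPS at 4, 12 and 24 h (panels), under 6 settings of the fit (x axis; the 11 arrays are those with a mean correlation under 0.9). At 24 h the count of lower genes went from 1252 to 2, 4, 70, 184 and 193 under the other settings, while at 4 h between 672 and 3106 genes were lower under all of them.

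The later times were compared with each other to ask how transcripts differed between them. Of 19 cytokine genes 15 fell from 4 h to 24 h (median -2.46, adjusted p = 0.00458 with an estimated correlation). CXCL10 fell 40.6-fold (-5.34 ± 0.36), CXCL11 21.6-fold, IL6 21.2-fold and CXCL2 18.9-fold, and the adhesion gene SELE fell 16.9-fold, each lower in 12 of 12 volunteers. Their 24 h means, from 5.14 for CXCL11 to 7.35 for CXCL2, also lay under every array median, so these folds are approximate. DDIT4L, PRAG1, IRAG2, FAM124B and CX3CR1, the receptor of CX3CL1, rose between 3.73- and 4.47-fold from 4 h to 24 h. Of the 1042 genes that rose at 4 h, 561 were lower at 12 h and 788 (75.6%) were lower at 24 h by the direct test. Of the 2144 that fell, 780 were higher at 12 h and 888 (41.4%) at 24 h. These genes were chosen on the same 4 h arrays as the direct test used, which by itself favours such reversals, and no value for unchanged genes was computed for these shares. Between 4 h and 12 h, 16 of 19 NF-kB genes, 14 of 19 cytokine genes, 10 of 16 immediate early genes and 9 of 16 clock genes fell, while 3 clock genes rose (adjusted p = 8.01e-05, 0.00273, 0.0337 and 0.0232 with an estimated correlation). Of 22 glucocorticoid response genes 14 fell and 1 rose (adjusted p = 0.0184 with an estimated correlation). Of 42 interferon response genes 21 fell (adjusted p = 0.158 with an estimated correlation), while 7 of 18 macrophage markers rose (adjusted p = 0.804 with an estimated correlation). Between 4 h and 24 h, 36 of 42 interferon response genes fell, and of 27 acute phase and STAT3 genes 14 fell and 1 rose (each adjusted p = 0.0295 with an estimated correlation). Over the same times 7 of 9 T and NK cell markers rose (median 1.02, adjusted p = 0.242 with an estimated correlation).

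Between 12 h and 24 h the clock genes returned: 11 of 16 rose and 4 fell (median 0.73, adjusted p = 0.00037 with an estimated correlation). CIART rose 10.4-fold (3.38 ± 0.21, adjusted p = 1.11e-15), DBP 3.97-fold, TEF 3.43-fold, PER3 3.33-fold and NR1D2 3.11-fold, each higher in 12 of 12 volunteers. PLA1A fell 7.89-fold (-2.98 ± 0.27, lower in 12 of 12), ANGPTL8, a feeding-induced inhibitor of lipoprotein lipase, 6.57-fold, and PNPLA3, MT1M and CXCL11 between 3.21- and 3.88-fold. Of 19 unfolded protein and heat shock genes 7 fell (median -0.25, adjusted p = 0.0358 with an estimated correlation), and of 21 lipolysis and lipid droplet genes 8 fell (median -0.37, adjusted p = 0.186 with an estimated correlation). At 12 h against 4 h 1079 genes were higher and 805 lower, at 24 h against 4 h 1198 and 1492, and at 24 h against 12 h 119 and 514. Without the volunteer block these counts were 323 and 337, 353 and 599, and 22 and 74. For 12 h against 4 h they were 2112 and 1582 with array weights, and 1637 and 1244 without the 11 arrays. They were 562 and 522 without the 4 volunteers of high control ratio, and 896 and 996 with arrays centred on their median. Whether more genes rose or fell thus depended on the scaling. For 24 h against 4 h the counts were 741 and 939 with only the arrays of both times, and 634 and 1245 without the 4 volunteers. They were 2698 and 2028 with array weights, and 1947 and 1441 without the 11 arrays. In these last settings more genes were higher than lower, unlike in the main fit. For 24 h against 12 h the counts were 960 and 1060 with array weights, and 28 and 140 with only the arrays of both times. They were 36 and 276 without the 4 volunteers, and 438 and 501 without the 11 arrays. In that comparison 78 genes were higher without volunteer 10 and 322 lower without volunteer 1.

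Calls at different times shared genes. At 4 h and 12 h, 304 genes rose at both times and 611 fell at both, against 57.2 and 237.5 for independent lists, which leaves the shared arrays before LPS out of account. In 20 simulations of unchanged groups with shared arrays limma gave a mean overlap of 0, but unchanged groups give few calls, so this is no measure of the overlap to be expected. Opposite directions were called for 29 genes. The correlation of the changes across genes, which are not independent replicates, was 0.576 (0.495 in the simulations) and their covariance 0.0772 (0.0088 in the simulations). With the volunteers split so that no array before LPS was shared, the correlation was 0.431 and 0.44. At 4 h and 24 h, 45 genes rose at both times and 436 fell at both (11.8 and 270 for independent lists). Their covariance was 0.0379 (0.009 in the simulations), with a correlation of 0.329 (0.476 in the simulations), or 0.122 and 0.196 with the split. At 12 h and 24 h, 59 rose at both times and 427 fell at both (6.2 and 138.7 for independent lists). Here the covariance was 0.0435 (0.009 in the simulations), with a correlation of 0.579 (0.475 in the simulations), or 0.191 and 0.342 with the split. With the split and limma, 69 genes rose and 51 fell at both 4 h and 12 h, and 1 rose at both times of each of the other pairs.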

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

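Which genes changed direction between times was counted after the changes were known. At 4 h and 12 h 29 genes were called in opposite directions with a called direct difference, of which 17 rose and then fell and 12 fell and then rose. BMAL1 went from -1.53 to 0.99, NPAS2 from -0.91 to 0.65, PPARGC1B from -1.03 to 0.59 and PER2 from 0.43 to -1.24, and 24 of the 29 were still called at 12 h without the 11 arrays of low mean correlation. At 4 h and 24 h the count was 33, among them SELE and VCAM1, which rose and then fell. Without those arrays 1 of the 33 was still called at 24 h (MYO10, adjusted p = 0.0367, chosen after its values were seen), and SELE (0.0634) and VCAM1 (0.33) were not. At 12 h and 24 h there were 4 such genes (PNPLA3, AACS, TMEM138 and FITM2), and 0 were still called at 24 h with limma without those arrays.

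Lists also differed between times. Camera called 10 lists for 12 h against 4 h, 13 for 24 h against 4 h and 15 for 24 h against 12 h, and with an estimated correlation 5, 5 and 2. The T and NK cell markers were called lower at 4 h and higher at 24 h (median 0.20 at 24 h). Lipolysis and lipid droplet genes were called higher at 12 h and lower at 24 h (median -0.27). Oxidative phosphorylation genes were called lower at 12 h and above the other genes at 24 h. At 24 h their median was 0.0118 against -0.09 for all genes, and 0 of 43 were called with limma. They were thus not shown to lie above their level before LPS. With an estimated correlation neither call of any of these 3 lists held (adjusted p = 0.636 and 0.546 for T and NK cell, 0.75 and 0.546 for lipolysis, and 0.75 and 0.689 for oxidative phosphorylation).

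Probe sets without a gene symbol also changed. Among the 2023 of them that passed the intensity filter, 289 were higher and 321 lower at 4 h, 113 and 62 at 12 h, and 19 and 70 at 24 h. What they measure was not analysed here.

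The tests of the genes lower at 24 h were chosen only after the result was seen. Without the 11 poorly correlated arrays 70 genes were lower, which lay inside 50 random leave-outs of as many arrays per time (5 to 1494), as had been written for the case that the arrays were not the cause, but a range that wide decides nothing, and a second test was added. In it the median change of the 1252 genes went from -0.437 to -0.174, closer to 0 than in every random leave-out (-0.583 to -0.212). The genes higher at 4 h went up to 1423. The size of these falls thus rested in part on the 11 arrays. These included every array of volunteers 2 and 3, while the random leave-outs were drawn within each time across all volunteers. Poor arrays therefore cannot be told apart from volunteers who differed from the others. For RNA quality before LPS, the 928 genes lower without the 4 volunteers of high control ratio also decide nothing beside random leave-outs of 30 to 1236, but the median change of the 1252 genes without them was -0.496, no closer to 0, which argues against those volunteers as the whole cause. With the control ratio as a covariate the median change was -0.376 against -0.437. The median of the single-gene SEs was 0.138 against 0.127, and 182 of the 1252 calls were kept. Calls ended with a smaller change and a larger error, so a part played by RNA quality stays open.

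The tests of the clock genes at 12 h were chosen only after the result was seen. With the control ratio as a covariate the median change of the 11 genes that fell was -1.56 against -1.35 without it. The median of their single-gene SEs was 0.16 against 0.14. Of the 11 calls 10 were kept. This argues against RNA quality before LPS, as far as the control ratio measures it, as the cause of these falls. For time of day of the biopsy, 0 of the 16 clock genes were called at 24 h with limma (3 at an unadjusted p under 0.05). A biopsy at another hour could give this pattern and so could a response to LPS that had passed by 24 h. The 2 cannot be told apart without volunteers who received no LPS.

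The tests of the leukocyte markers at 4 h were chosen only after the result was seen. Relative to all genes the neutrophil and monocyte markers shifted by 0.88 (SD 0.91, higher in 11 of 14, exact two-sided p = 0.00403) and the T and NK cell markers by -0.69 (SD 0.80, lower in 12 of 14, exact two-sided p = 0.00403). Red blood cell markers shifted by 0.17 (SD 0.68, higher in 8 of 14, exact two-sided p = 0.365). The opposite shifts of the leukocyte markers argue against the amount of blood in the biopsy as the only cause. More blood of unchanged makeup would move both the same way. Whether the amount of blood had a part beside another change stays open. The difference between the shifts was 1.57 (SD 0.985, higher in 14 of 14, exact two-sided p = 0.000122, the smallest possible). A change in the makeup of blood leukocytes could give this difference, and so could a change of cells within the tissue.

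Chance assignment of the times was tested with 100 swaps of labels within volunteers, the real labels included, a test fixed before the result was seen. In each of the 6 comparisons 1 of the 100 assignments, the real labels, gave as many calls as were seen. A chance assignment was thus unlikely to give as many, but 100 draws cannot exclude it. The real count and the highest other were 3186 and 1398 at 4 h, 1647 and 219 at 12 h, 1365 and 1149 at 24 h, 1884 and 891 for 12 h against 4 h, 2690 and 1953 for 24 h against 4 h, and 633 and 379 for 24 h against 12 h. Between 6 and 16 of the other assignments called any gene. Which swaps these were, and why they called genes, was not examined.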

How the results depend on the processing

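Of 253 named gene values under all settings, 7727 comparisons stayed the same, 767 were weaker, 19 stronger and none reversed. Volunteers 3, 11 and 14 were left out in turn and also for marks in titles or separate array numbers. These are the same fits, and the totals count them in both forms. The values at 24 h, 53 of 67 called, gave way most in 3 settings: with only both groups' arrays 49 of them were weaker, without the volunteer block 47 and without the 11 arrays 39. The cause of each shift below was not tested. Without the volunteer block the genes higher and lower were 551 and 672 at 4 h, 85 and 94 at 12 h, 9 and 4 at 24 h, 323 and 337 for 12 h against 4 h, 353 and 599 for 24 h against 4 h, and 22 and 74 for 24 h against 12 h. With the volunteers that had all 4 times, 712 genes were lower at 12 h and 768 at 24 h. With only both groups' arrays in the fit the counts were 5 and 2 at 24 h, 741 and 939 for 24 h against 4 h, and 28 and 140 for 24 h against 12 h. The 75th percentile filter, which by construction tests fewer genes (6119), gave 674 and 1093 at 4 h, 655 lower at 12 h, 534 and 506 for 12 h against 4 h, 587 higher for 24 h against 4 h and 62 higher for 24 h against 12 h. The control ratio as a covariate gave 344 and 469 at 12 h and 18 and 193 at 24 h. Without the volunteer with a suffix in the titles, who is volunteer 11, 609 were lower at 12 h. Leaving out each volunteer in turn gave 609 to 1320 lower at 12 h, 59 to 132 higher and 537 to 1392 lower at 24 h, and 78 to 169 higher and 322 to 570 lower for 24 h against 12 h.

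The next 3 settings were chosen after the data were seen. Array weights gave 1613 higher at 4 h, 962 higher at 12 h, and 75 and 184 at 24 h, with 6 lists called at 24 h. The counts with these weights were 2112 and 1582 for 12 h against 4 h. They were 2698 and 2028 for 24 h against 4 h, and 960 and 1060 for 24 h against 12 h. With array weights the oxidative phosphorylation list median log2 change at 24 h reversed to -0.0689. Without the 11 arrays the counts were 47 and 70 at 24 h, with 5 lists at 24 h. They were 1637 and 1244 for 12 h against 4 h. For 24 h against 4 h and against 12 h they were 1947 and 1441, and 438 and 501. Without the 4 volunteers of high control ratio 922 were lower at 4 h, 153 and 143 were higher and lower at 12 h, 48 higher at 24 h, 562 and 522 for 12 h against 4 h, 634 higher for 24 h against 4 h, and 36 and 276 for 24 h against 12 h. For the lists, an estimated correlation left 6, 5 and 0 called at 4, 12 and 24 h with camera (3 at an unadjusted p under 0.05 at 24 h), and fry called 7 at 12 h.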

Other observations

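The genes of 7 metallothioneins, small proteins that bind zinc and copper, were chosen after their values were seen. MT1M rose by 3.08 at 4 h, 2.37 at 12 h and 0.59 at 24 h, MT1G by 2.30, 1.54 and 0.86, and MT2A by 1.92, 1.47 and 0.76. MT1X, MT1H, MT1F and MT1E rose by 1.94, 1.94, 1.91 and 1.74 at 4 h and by 0.59, 0.66, 0.77 and 0.62 at 24 h. All 7 were called at each time and were higher in 14 of 14 volunteers at 4 h and 12 h. The genes are close paralogs whose transcripts can hybridise to each other's probes, so the 7 values are not independent. Without the 11 arrays of low mean correlation they were still called at 24 h, with values from 0.53 (MT1X) to 0.87 (MT1G). MT1X lost its call with array weights, and in the fit of only the arrays of both times MT1M (adjusted p = 0.134), MT1H (0.0686), MT1G (0.0649) and MT1F (0.0859) lost theirs, so that MT2A and MT1E were called at 24 h under all 3 settings. Over the scalings tried the lowest value at 24 h was 0.44, for MT1M.

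The time courses of 5 further genes were chosen after their values were seen. ANGPTL8, which restrains lipoprotein lipase after feeding, was at -0.14 at 4 h (adjusted p = 0.739), rose by 1.97 ± 0.29 at 12 h in 13 of 14 volunteers, and was at -0.75 at 24 h (adjusted p = 0.0955). CX3CR1, a receptor of patrolling monocytes and cytotoxic lymphocytes, fell by 1.46 at 4 h in 13 of 14 volunteers and was at 0.20 at 12 h and 0.44 at 24 h, while the gene of its ligand, CX3CL1, rose by 3.57 ± 0.20 at 4 h and was at 0.36 at 12 h (adjusted p = 0.222) and -0.36 at 24 h (adjusted p = 0.245). TRIL fell by 2.80 ± 0.22 at 4 h, was at -0.39 at 12 h (adjusted p = 0.215) and fell by 0.96 at 24 h (adjusted p = 0.00791), a call that was not kept under both array weights and leaving out the 11 arrays. FCGR2A, an Fc receptor of myeloid cells, was at 0.15 at 4 h (adjusted p = 0.552), rose by 0.77 at 12 h in 13 of 14 volunteers and was at 0.45 at 24 h (adjusted p = 0.108).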
